A study of Arabidopsis thaliana with 9 samples.

How the data were processed

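Total RNA of the vegetative part of seedlings grown in vitro was hybridised to Affymetrix ATH1 arrays, per the labels' protocols, with plants kept at 22 °C under 16 h of light and 8 h of dark. The 9 arrays are 3 biological repeats each of WT, scr and shr, and groups and repeat numbers were taken from the sample titles. The deposited values are on the log2 scale and were made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, normalises quantiles between arrays and summarises the probes of a set. Its version, the mapping of probes to genes and any filter are not given in the sources used here. That the values are log2 was read from their range of 2.90 to 14.03.

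The table held 1 row for each of 20777 loci, named by locus code, so no choice between probe sets was needed and control probe sets did not enter. Gene symbols came from a reference gene table of the assembly TAIR10.1, used for names and for the order of neighbouring genes only: 20508 loci matched, 8945 had a symbol other than the locus code and 269 did not match. A symbol shared by 2 loci was replaced by the locus code. No coordinates are given, since the build behind the probe mapping is not stated. Plastid (73) and mitochondrial (31) loci stayed in the table. No 2 arrays held identical values.

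Changes were computed with R 4.3.3 and limma 3.58.1, as 1 linear model on the log2 values of all 9 arrays with a mean per genotype, so that the 3 groups share an estimate of the spread (6 residual and 2.99 prior degrees of freedom after eBayes). The 3 comparisons were scr against WT, shr against WT and shr against scr. P-values are two-sided and adjusted with Benjamini and Hochberg's method over all 20777 loci of a comparison, with a threshold of 0.05. No filter on dim loci was applied. The repeat numbers were taken to pair the scr and WT arrays, since the deviations from the group means correlated over 0.1 in all 3 pairs of equal number (0.277, 0.138 and 0.107). This comes from the data, as the labels give no shared batch or day. That the pairs are judged within each comparison was decided after the fits had been seen. In shr against WT 1 of 3 pairs and in shr against scr 2 of 3 pairs did so, and there the numbers were not taken as pairs. The main fit holds no term for the repeat number in any comparison, so its scr results are unpaired. The pairing enters only the alternative fit with the repeat number as a block. Errors of single genes are the standard errors of limma's moderated fit, and SDs are over the 3 arrays of a group.

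The procedure was tested on simulated data, in 20 draws with 200 of 20777 loci changed. For scr against WT it recovered 61.2% of 1.5-fold and 91.3% of 2-fold changes, with 5.56% false calls. The corresponding shares were 60.4%, 92.1% and 4.82% for shr against WT, and 60.8%, 90.7% and 4.94% for shr against scr. These shares describe the simulated data only. Whether they hold for the real arrays, among which shr replicate 3 stood apart, was not tested. In scr against WT the real count was 76 with all arrays, 17 without scr replicate 3 and 595 without shr replicate 3.

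Before the data were examined, 28 gene lists were fixed by locus: SHR-SCR network, G1/S regulators, DNA replication, replication-dependent histones, mitosis, CDK inhibitors and endocycle, DNA damage response, leaf growth regulators, cell wall expansion, photosynthesis, anthocyanin and flavonoid synthesis, phosphate starvation, nitrate response, iron deficiency, sugar starvation, abscisic acid and water deficit, salicylic acid defence, jasmonate and wounding, cytokinin response, auxin response, gibberellin, heat shock, circadian clock, senescence, root tissue markers, shoot meristem and boundary markers, flowering, and secondary wall and xylem markers. The lists of root, meristem, flowering, xylem and senescence genes check for other tissues. The clock list was meant to check for harvest time, but its mean can hide a shift of genes that move in opposite directions. Of 389 distinct loci in the lists, 345 were measured; MCM6, the ORC1 and CDKB1 genes, LDOX and most histone H4 genes were among those not measured here.

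Each list was tested in each comparison with limma's camera at a preset correlation of 0.01 between genes, adjusted over all 84 tests. Of these, 26 passed. With a correlation estimated per list none of the 84 passed (13 did at an unadjusted p under 0.05), and with fry, which asks whether a list's genes move one way without comparing them with other genes, 19 passed. Standard errors of list means are over members, which are correlated. No list past the threshold had a mean and a median of different sign.

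The rule for naming genes was fixed at the same time. It takes SCR, SHR and CYCD6;1, the 8 largest rises and 8 largest falls in each mutant against WT and the 5 and 5 between the mutants. These were taken among loci with a symbol that passed the threshold and whose 3 arrays per group did not overlap, which chance gives in 10% of loci for 3 arrays against 3. A symbol here is one in the symbol column of the reference table, so larger changes of loci without one were passed over. GGCT2;1, listed there by locus code only, is among these, although its rises would place it among the 8 in both mutants. From each list it takes up to 4 members with the smallest adjusted p. Some further list members are named as examples of their list.

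The alternatives tried were a second quantile normalisation, a common median for each array, leaving out the lower 40% of loci by mean signal, fits of only the 2 groups compared, eBayes with trend and robust options, array weights, the repeat number as a block, leaving out each array in turn, stricter thresholds, and limma's treat. A fit of the 2 groups compared without shr replicate 3, and camera with an estimated correlation without shr replicate 3 and with array weights, were added after the data were seen. The correlation of the mutants' changes was set beside 100 simulations of unchanged groups with shared WT arrays.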

Results

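Transcript levels were measured on Affymetrix ATH1 arrays in the vegetative part of Arabidopsis thaliana seedlings of the accession Col-0 at growth stage 1.04. The 9 arrays fell into 3 groups of 3 biological repeats: the wild type (WT), a mutant of SCARECROW (scr) and a mutant of SHORT-ROOT (shr). SHORT-ROOT (SHR) and SCARECROW (SCR) are GRAS transcription factors best known for patterning the ground tissue of the root. The series title puts the question of how both act on leaf growth and on passage through S phase. Each array gave 1 value for each of 20777 loci, between 2.90 and 14.03 on the log2 scale, and the number of arrays limits the precision. Across loci, which are not independent replicates, the 8 arrays other than shr replicate 3 correlated with each other at r = 0.983 to 0.997. The array of shr replicate 3 correlated with them at r = 0.970 to 0.979.

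The SHR transcript (AT4G37650) separated the shr arrays from all others. Its value was 6.61, 6.57 and 6.81 on the WT arrays, 6.40, 6.23 and 6.19 on the scr arrays, and 4.70, 4.73 and 4.89 on the shr arrays. SHR fell in shr against WT by 1.89 on the log2 scale (SE 0.10, 3 against 3 arrays, limma adjusted p = 2.87e-05), a level 3.72-fold below WT. The SCR transcript (AT3G54220) was 7.96, 7.99 and 7.94 on the WT arrays, 7.63, 7.44 and 7.13 on the scr arrays, and 7.60, 7.43 and 7.35 on the shr arrays. Its difference from WT was -0.57 (SE 0.12, limma adjusted p = 0.110) in scr, and in shr it fell by 0.51 (limma adjusted p = 0.0399). Between the mutants SCR differed by 0.06 (limma adjusted p = 0.847), so its transcript level does not separate scr from shr arrays and leaves the scr label unchecked. Where the probes of either gene lie relative to its mutation is not given in the sources used here. The call of SCR in shr was lost without WT replicate 1, 2 or 3, scr replicate 2, or shr replicate 2 or 3, with an adjusted p of up to 0.126. CYCD6;1 (AT4G03270), a D-type cyclin that SHR and SCR activate in the root, had values of -0.32 in scr (limma adjusted p = 0.285) and -0.34 in shr (limma adjusted p = 0.0834) against WT.

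**Figure D1:**
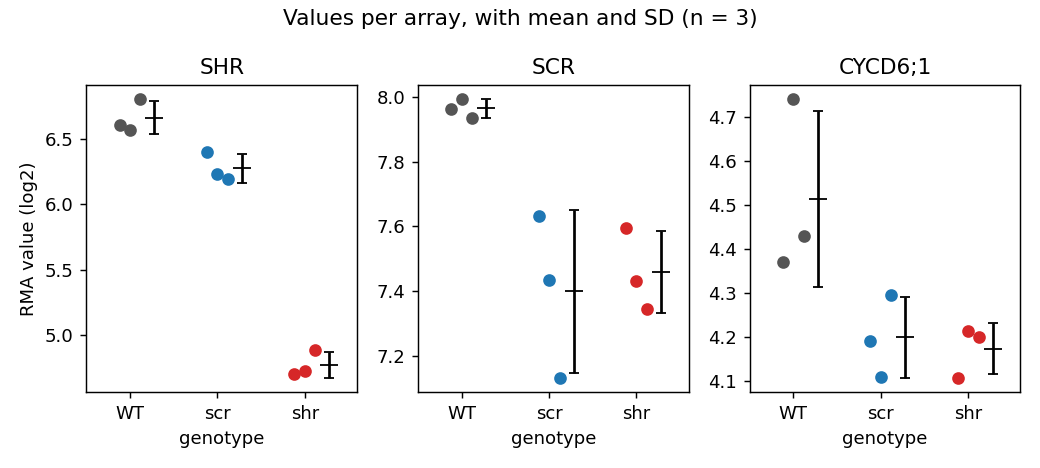
RMA values (log2) of SHR, SCR and CYCD6;1 on each array, by genotype, with the mean and SD of 3 arrays. SHR lies between 4.70 and 4.89 on the shr arrays and between 6.19 and 6.81 on the other 6, while the SCR values of scr (7.13 to 7.63) and shr (7.35 to 7.60) overlap.

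In scr against WT, the comparison for the SCR mutation, LSU1 (AT3G49580) rose furthest among genes with a symbol past the threshold, by 2.89 (SE 0.45). LSU1 is a gene of the response to low sulfur. SDI1 had a larger value, 3.04, but did not pass (limma adjusted p = 0.0649). BGLU28 (AT2G44460), a beta-glucosidase gene, rose by 2.51 (SE 0.18), a 5.70-fold change. NF-YA2 (1.93, SE 0.13) and NF-YA3 (1.43, SE 0.08), which encode subunits of the CCAAT-binding factor NF-Y, rose as well. So did BGLU11 (1.86), AHP4 (1.73), a phosphotransfer protein gene of cytokinin signalling, DR4 (1.70) and SULTR4;2 (1.30), a vacuolar sulfate transporter gene. PRA1.F1 fell by 2.09 (SE 0.15), and NAS3, a nicotianamine synthase gene, fell by 1.54. MSRB6, a methionine sulfoxide reductase gene, fell by 1.21. WRKY17 (-1.07), NET3A (-1.04), ARR15 (-0.86), a response regulator induced by cytokinin, HKT1 (-0.84), a sodium transporter gene, and HTA11 (-0.82), a histone H2A.Z gene, completed the 8 largest falls among genes with a symbol.

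In all, 76 of 20777 loci changed in scr (limma, adjusted p under 0.05), 49 higher and 27 lower, and 33 of these differed at least 2-fold. At an unadjusted p under 0.05 there were 2283 loci. Without WT replicate 1, 2 or 3 the count was 35, 23 or 22, and without scr replicate 1, 2 or 3 it was 34, 33 or 17. It was 595 without shr replicate 3 (323 higher and 272 lower) and 577 with WT and scr arrays alone. Without the lower 40% of loci by signal it was 55, with 44 higher and 11 lower. BGLU28, NF-YA2, NF-YA3, DR4, PRA1.F1 and MSRB6 kept their calls in all 9 fits that left out 1 array. The other 10 genes named above lost theirs in 2 to 7 of these fits. LSU1, AHP4, SULTR4;2 and WRKY17 did so without any 1 of the WT or scr arrays (adjusted p up to 0.164, 0.136, 0.142 and 0.178). ARR15 lost its call without any 1 of these or shr replicate 2 (up to 0.169), and HKT1 without WT replicate 2 or 3, any scr array, or shr replicate 1 or 2 (up to 0.153). The call of BGLU11 was lost without WT replicate 2 or 3 or any scr array (up to 0.0812), and that of NET3A without any WT array or scr replicate 2 or 3 (up to 0.0807). HTA11 lost its call without WT replicate 1 or 2 or scr replicate 3 (up to 0.0744), and NAS3 without WT replicate 3 or scr replicate 3 (up to 0.0546). With the replicate number as a block, LSU1 (adjusted p = 0.0660), SULTR4;2 (0.0582), WRKY17 (0.0957) and NET3A (0.0502) were past the threshold no longer, and 52 loci changed, 46 of them among the 76.

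The lists of mitosis, histone, DNA replication and CDK inhibitor genes shifted downwards in scr by small amounts at camera's preset correlation. The mitosis list had a mean change of -0.32 (SE over members 0.03, camera adjusted p = 2.41e-13; adjusted p = 0.110 with an estimated correlation). None of its 22 measured members passed over all genes, 15 were lower at an unadjusted p under 0.05, and 13 fell when adjusted over the list alone. Its lowest values included AUR2 at -0.57, KNOLLE, a syntaxin gene of cytokinesis, at -0.50, and CDKB2;1 at -0.48. Replication-dependent histone genes had a mean of -0.28 (SE 0.02, camera adjusted p = 6.14e-12; adjusted p = 0.0982 with an estimated correlation). Of these 16 measured members 0 passed over all genes, 14 at an unadjusted p under 0.05 and 12 adjusted over the list alone. The DNA replication list shifted by -0.14 (SE 0.03, camera adjusted p = 2.19e-04; adjusted p = 0.562 with an estimated correlation). Of its 24 measured members 0 passed over all genes, 3 at an unadjusted p under 0.05 and 1 adjusted over the list alone. For the CDK inhibitors and endocycle list the mean was -0.12 (camera adjusted p = 0.0224; adjusted p = 0.319 with an estimated correlation). Of its 18 measured members 0 passed over all genes or adjusted over the list alone, with 1 higher and 2 lower at an unadjusted p under 0.05. The DNA damage response list had a mean of -0.18 (camera adjusted p = 0.00756, and 0.411 with an estimated correlation). It shares TSO2 with the DNA replication list, CYCB1;1 with the mitosis list, and SMR5 and SMR7 with the CDK inhibitors and endocycle list. Of its 9 measured members 0 passed over all genes, 2 at an unadjusted p under 0.05 and 1 adjusted over the list alone. The call of the CDK inhibitor list was lost without WT replicate 1 (adjusted p = 0.0654) or scr replicate 3 (adjusted p = 0.171), and that of the DNA damage list without WT replicate 3 (adjusted p = 0.0619).

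Of the nutrient, hormone and stress lists, 5 shifted in scr. The phosphate starvation list had a mean change of 0.61 (SE 0.12, camera adjusted p = 2.22e-06; adjusted p = 0.504 with an estimated correlation). Of its 15 measured members 0 passed over all genes, 9 at an unadjusted p under 0.05 and 3 adjusted over the list alone. The values of MGD3, a galactolipid synthase gene, and SPX1 were 1.04 and 1.19. Anthocyanin and flavonoid genes had a mean of 0.94 (SE 0.11, camera adjusted p = 0.00461; adjusted p = 0.724 with an estimated correlation). Of these 13 measured members 0 passed over all genes or adjusted over the list alone, and 1 at an unadjusted p under 0.05. The call was lost without WT replicate 2 (adjusted p = 0.0730) or scr replicate 1 (adjusted p = 0.102). Cytokinin response genes had a mean of -0.40 (SE 0.12, camera adjusted p = 1.56e-05; adjusted p = 0.319 with an estimated correlation). ARR15 fell over all genes and 3 of 10 fell when adjusted over the list alone. The auxin response list had a mean of -0.35 (SE 0.12, camera adjusted p = 0.00461; adjusted p = 0.504 with an estimated correlation). Of its 13 measured members 0 passed over all genes, and 4 were lower both at an unadjusted p under 0.05 and adjusted over the list alone. Heat shock genes had a mean of 0.26 (SE 0.09, camera adjusted p = 5.42e-04; adjusted p = 0.199 with an estimated correlation). HSP17.6B rose by 0.94 over all genes and 2 of 12 rose when adjusted over the list alone. Its call was lost without WT replicate 1, 2 or 3 or scr replicate 1 or 3 (adjusted p up to 0.127), and with the replicate number as a block (adjusted p = 0.0534).

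In shr against WT, the comparison for the SHR mutation, LTP4 (AT5G59310), a lipid transfer protein gene, rose furthest among genes with a symbol, by 3.87 (SE 0.33), a 14.6-fold change. LSU1 rose by 3.68 (SE 0.45), BGLU28 by 3.63 (SE 0.18) and SDI1, a sulfur deficiency gene, by 3.62 (SE 0.55). ASN1, an asparagine synthetase gene induced by low sugar, rose 8.03-fold. PS2 (2.91, SE 0.66), a phosphatase gene of phosphate starvation, BGLU11 (2.76) and EARLI1 (2.74) followed. The largest falls among genes with a symbol were AT1G06080 (-3.12, SE 0.34), a fatty acid desaturase gene, PGL5 (-2.68), a 6-phosphogluconolactonase gene, PRA1.F1 (-2.59) and the purple acid phosphatase gene PAP8 at AT2G01890 (-2.53). They were followed by THA2 (-2.23, SE 0.08), a threonine aldolase gene, SHR itself, CYP707A2 (-1.87), an abscisic acid hydroxylase gene, and PRE1 (-1.83), a growth-promoting bHLH gene.

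In all, 1691 of 20777 loci changed in shr (limma, adjusted p under 0.05), 904 higher and 787 lower, and 276 of these differed at least 2-fold. With each array shifted to a common median, which placed the median of all loci at -0.07 in shr against WT, 1966 loci changed and the share of higher calls was 34.9% in place of 53.5%. The count was 859, 654 or 750 without WT replicate 1, 2 or 3. It was 1029 without shr replicate 2, 2643 without shr replicate 3, and 807 with WT and shr arrays alone. Of the 16 genes named above, 13 kept their calls in all 9 fits that left out 1 array. ASN1 lost its call without WT replicate 1, 2 or 3 (adjusted p up to 0.0786), and EARLI1 without WT replicate 1, 2 or 3 or shr replicate 2 (up to 0.0755). PS2 lost its call in 7 fits, all but those without scr replicate 1 or shr replicate 3 (up to 0.113). On shr replicate 3, which stands apart, ASN1 lay at 10.02 against 8.01 and 7.07 on the other shr arrays, and PS2 at 5.51 against 8.35 and 8.15.

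In shr the mitosis, histone and DNA replication lists shifted downwards at camera's preset correlation. In the mitosis list 11 of 22 measured members fell over all genes, 18 fell when adjusted over the list alone, and none rose. Its mean change was -0.43 (SE 0.04, camera adjusted p = 2.82e-11; adjusted p = 0.117 with an estimated correlation). CYCB1;1, a mitotic cyclin gene, fell by 0.72 (SE 0.11, limma adjusted p = 0.00672), KNOLLE fell by 0.62, TPX2, a spindle assembly gene, by 0.59, and PLE, a gene of the cytokinetic microtubule array, by 0.57. Among replication-dependent histone genes, 9 of 16 fell over all genes and 13 adjusted over the list alone. The list had a mean of -0.36 (SE 0.04, camera adjusted p = 1.25e-08; adjusted p = 0.117 with an estimated correlation). The histone H4 gene HIS4 fell by 0.63, the histone H3 gene AT5G10400 by 0.56 and HTA13 by 0.41. In the DNA replication list 3 of 24 members fell over all genes and 12 adjusted over the list alone. The list had a mean of -0.27 (SE 0.03, camera adjusted p = 3.15e-06; adjusted p = 0.451 with an estimated correlation). The 3 genes were CDC6A (-0.60), a replication licensing gene, PCNA2 (-0.47), the sliding clamp of DNA polymerase, and MCM7 (-0.41), a subunit of the replicative helicase. MCM7 and PCNA2 kept their calls only without shr replicate 2 (adjusted p up to 0.159 and 0.149 in the other fits), and CDC6A lost its call without WT replicate 2 or 3 or shr replicate 2 (up to 0.0705). HTA13 and AT5G10400 lost theirs without WT replicate 2 or 3 (up to 0.0552 and 0.0566), and HIS4 without WT replicate 1, 2 or 3 (up to 0.0813).

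The DNA damage response list, with its shared members, had a mean of -0.34 in shr (SE 0.06, camera adjusted p = 5.42e-04; adjusted p = 0.319 with an estimated correlation). Only CYCB1;1 of the 9 fell over all genes and 6 fell adjusted over the list alone. The SHR-SCR network list, which holds SHR itself, had a mean of -0.48 (SE 0.19, camera adjusted p = 0.00239; adjusted p = 0.309 with an estimated correlation). Of its 10 members SHR, SCR and SNE (-0.42) fell and MGP (0.34) rose over all genes, and 7 fell and 1 rose adjusted over the list alone. The call of SNE was lost in 7 of the 9 fits without 1 array (adjusted p up to 0.116), all but those without WT replicate 2 or shr replicate 3. That of MGP was lost without WT replicate 1, 2 or 3 or shr replicate 2 (up to 0.0955). The same list had a mean of -0.12 in scr (camera adjusted p = 0.145). There 0 of 10 members passed over all genes, 3 at an unadjusted p under 0.05 and 3 adjusted over the list alone. G1/S regulators had a mean of -0.09 in scr (camera adjusted p = 0.0814) and -0.05 in shr (camera adjusted p = 0.677). In shr CYCD3;2 fell by 0.54, as 1 of 17 members over all genes and also adjusted over the list alone. CYCD3;2 lost its call without WT replicate 1, 2 or 3, scr replicate 2 or 3, or shr replicate 2 (adjusted p up to 0.124). In the CDK inhibitors and endocycle list, with a mean of -0.05 in shr (camera adjusted p = 0.676), KRP3 fell by 0.44 over all genes and 0 of 18 passed adjusted over the list alone. KRP3 lost its call without WT replicate 1, 2 or 3, scr replicate 2, or shr replicate 1 or 2 (adjusted p up to 0.134).

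**Figure D2:**
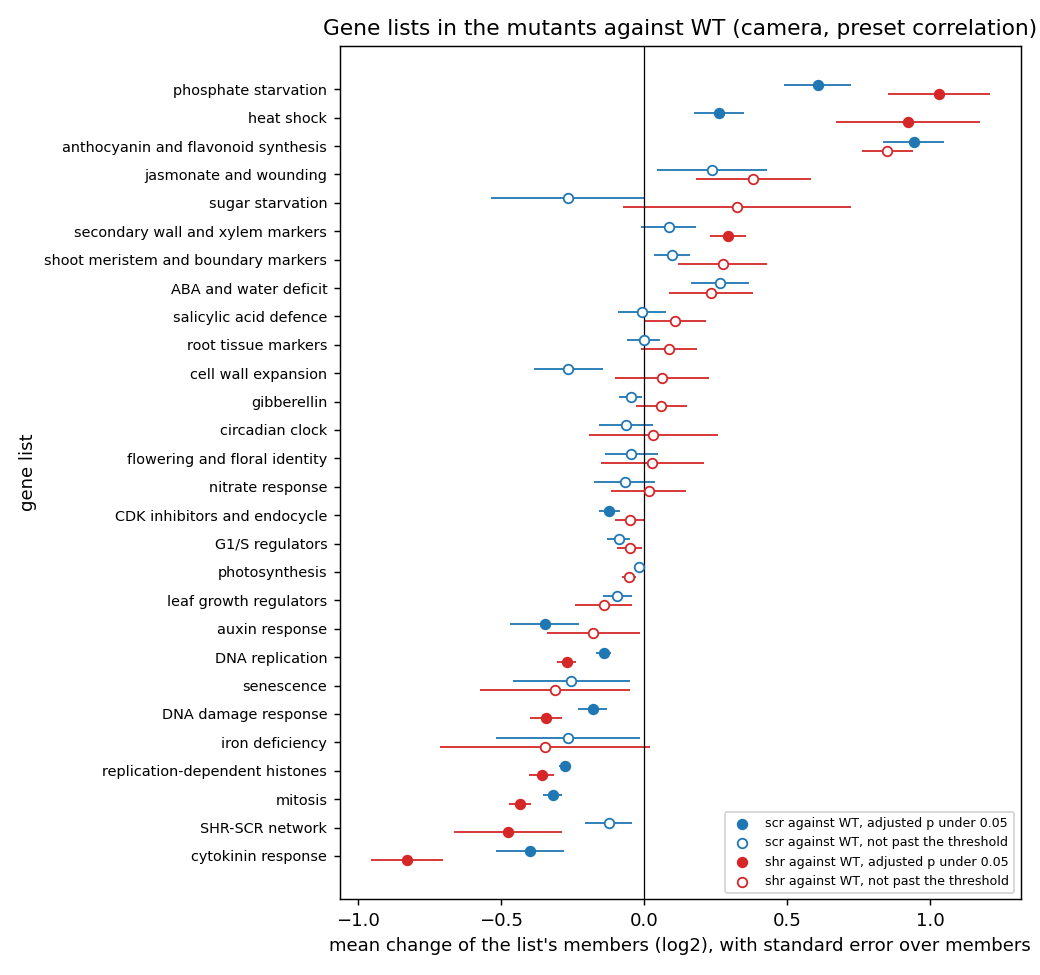
Mean change (log2) of the measured members of each gene list in scr and in shr against WT, with the standard error over members; filled points passed camera's test with a preset correlation. The mitosis list lies at -0.32 in scr and -0.43 in shr, the phosphate starvation list at 0.61 and 1.03.

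Among the lists past the threshold in shr, those of phosphate starvation, heat shock and cytokinin response had the largest mean changes. In the phosphate starvation list 7 of 15 members rose over all genes and 13 adjusted over the list alone. The list had a mean of 1.03 (SE 0.18, camera adjusted p = 1.45e-08; adjusted p = 0.438 with an estimated correlation). MGD3 rose by 2.06, MGD2 by 1.33 and PLDZ2, a phospholipase gene, by 1.16. The mean of this list over WT was 1.40 and 1.33 on shr replicates 1 and 2 and 0.36 on shr replicate 3. Of the cytokinin response genes 8 of 10 fell over all genes and 9 adjusted over the list alone. The list had a mean of -0.83 (SE 0.13, camera adjusted p = 1.25e-08; adjusted p = 0.194 with an estimated correlation). The response regulator genes ARR16, ARR5 and ARR6 fell by 1.57, 1.23 and 0.86. The list's mean over WT was -0.61, -0.80 and -1.08 on shr replicates 1, 2 and 3. Of the heat shock genes 6 of 12 rose over all genes and 9 adjusted over the list alone. The list had a mean of 0.92 (SE 0.25, camera adjusted p = 8.49e-09; adjusted p = 0.0982 with an estimated correlation). HSP17.6A, whose level on the WT arrays (3.51 to 3.80) lies near the lowest value in the table, rose by 2.72, HSP90.1 by 1.66 and HSP17.6B by 1.58. Of the 3 secondary wall cellulose synthase genes used as xylem markers, CESA7 rose by 0.42 over all genes and all 3 rose adjusted over the list alone. The mean was 0.29 (camera adjusted p = 0.0298; adjusted p = 0.319 with an estimated correlation). That list lost its call without WT replicate 2 (adjusted p = 0.0656), shr replicate 2 (0.0589) or shr replicate 3 (0.0647). CESA7 kept its call only without WT replicate 3 or shr replicate 3 (up to 0.151 in the other 7 fits). In scr the list had a mean of 0.09 (camera adjusted p = 0.429).

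Anthocyanin and flavonoid genes had a mean of 0.85 in shr (SE 0.09, camera adjusted p = 0.0503), with 0 of 13 members passing over all genes or adjusted over the list alone. Over the WT mean this list lay at 2.17 and 1.41 on shr replicates 1 and 2 and at -1.03 on shr replicate 3. Without shr replicate 3 its mean was 1.79 (adjusted p = 1.06e-09; adjusted p = 0.323 with an estimated correlation). Sugar starvation genes had a mean of -0.27 in scr (camera adjusted p = 0.811) and 0.33 in shr (camera adjusted p = 0.548). ASN1 rose in shr as 1 of 8 over all genes and also adjusted over the list alone. By array this list lay at -0.38 and -0.48 on shr replicates 1 and 2 and at 1.84 on shr replicate 3. The auxin response list lay at -0.49 and -0.39 on shr replicates 1 and 2 and at 0.34 on shr replicate 3. Its mean was -0.18 in shr (camera adjusted p = 0.173). In it SAUR-AC1 (-1.08) and IAA1 (-0.63) fell over all genes, and 4 fell and 1 rose adjusted over the list alone. Without shr replicate 3 its mean was -0.44 (adjusted p = 0.00280; adjusted p = 0.293 with an estimated correlation). SAUR-AC1 lost its call without WT replicate 1, 2 or 3 or shr replicate 2 (up to 0.0612) and IAA1 without WT replicate 1, 2 or 3, scr replicate 3 or shr replicate 1 (up to 0.103). Abscisic acid and water deficit genes had means of 0.27 in scr (camera adjusted p = 0.105) and 0.23 in shr (camera adjusted p = 0.409). In shr LTI30 (1.80) and COR15A (0.93) rose over all genes, and 3 of 17 rose and 1 fell adjusted over the list alone. COR15A kept its call only without shr replicate 3 (up to 0.142 in the other 8 fits). Without shr replicate 3 the list's mean was 0.27 in scr (adjusted p = 0.0135; adjusted p = 0.449 with an estimated correlation) and 0.51 in shr (adjusted p = 0.00387; adjusted p = 0.383 with an estimated correlation).

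**Figure D3:**
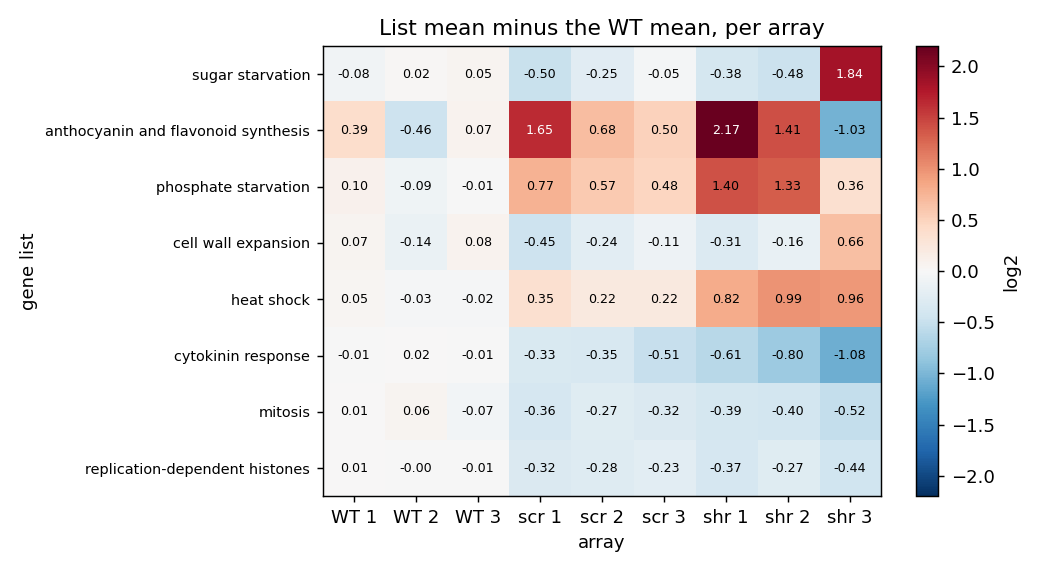
Mean of each gene list on each of the 9 arrays minus the WT mean (log2), as colour and number. On shr replicate 3 the anthocyanin list lies at -1.03 and the sugar starvation list at 1.84, against 2.17 and -0.38 on shr replicate 1.

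Several growth and development genes changed in shr within lists that did not pass as a whole. Of all 20777 loci 1691 were called in shr. Whether any of these lists holds a larger share of calls than that was not tested, so they are given as single genes. Leaf growth regulators had means of -0.09 in scr (camera adjusted p = 0.180) and -0.14 in shr (camera adjusted p = 0.180). In shr AN3, a co-activator gene of leaf cell proliferation, fell by 1.29 and ARGOS, an auxin-inducible gene of organ size, by 1.08. They were 2 of 19 members that fell over all genes, and 3 fell adjusted over the list alone. The cell wall expansion list had means of -0.27 in scr (camera adjusted p = 0.201) and 0.06 in shr (camera adjusted p = 0.808). In it the expansin genes EXPA8 (-1.13) and EXPA11 (-0.74) fell and CESA3 (0.51) rose in shr, both over all genes and adjusted over the list alone. By array it lay at -0.31, -0.16 and 0.66 on shr replicates 1, 2 and 3. Without shr replicate 3 its mean in scr had an adjusted p of 0.0429 (adjusted p = 0.383 with an estimated correlation). EXPA11 lost its call without WT replicate 1, 2 or 3 or shr replicate 1 (up to 0.0985), and CESA3 without WT or scr replicate 1, 2 or 3 (up to 0.118). Shoot meristem and boundary markers had means of 0.10 in scr (camera adjusted p = 0.337) and 0.28 in shr (camera adjusted p = 0.107). In shr the KNOX genes BP (1.26) and STM (0.79) and the receptor kinase gene CLV1 (0.36) rose, 3 of 9 over all genes and adjusted over the list alone. CLV1 kept its call only without scr replicate 1 or shr replicate 1 (up to 0.144 in the other 7 fits). The flowering list had means of -0.05 in scr (camera adjusted p = 0.791) and 0.03 in shr (camera adjusted p = 0.963). In shr the floral repressor gene FLC rose by 1.01 and SOC1, a floral activator gene that FLC represses, fell by 0.81, over all genes and adjusted over the list alone. SOC1 lost its call without WT replicate 1 or 3 (up to 0.0598).

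Root tissue markers had means of -0.00 in scr (camera adjusted p = 0.967) and 0.09 in shr (camera adjusted p = 0.769). PYK10, a beta-glucosidase gene of root and hypocotyl, rose by 0.84 in shr as 1 of 10 over all genes and adjusted over the list alone. Jasmonate and wounding genes had means of 0.24 in scr (camera adjusted p = 0.173) and 0.38 in shr (camera adjusted p = 0.0788). LOX2, a lipoxygenase gene, rose by 1.27 in scr and 1.28 in shr, and OPR3 rose by 0.60 in shr, as 1 and 2 of 8 members over all genes. Adjusted over the list alone, 1 rose and 1 fell in scr, and 5 rose and 1 fell in shr. LOX2 in scr lost its call without any 1 of the WT or scr arrays (up to 0.121), and OPR3 kept its call only without shr replicate 3 (up to 0.142 in the other 8 fits). Without shr replicate 3 the list's mean was 0.24 in scr (adjusted p = 0.0364; adjusted p = 0.217 with an estimated correlation) and 0.49 in shr (adjusted p = 0.00577; adjusted p = 0.172 with an estimated correlation). Salicylic acid defence genes had means of -0.01 in scr (camera adjusted p = 0.849) and 0.11 in shr (camera adjusted p = 0.337). EDS5 rose by 0.77 in shr as 1 of 15 over all genes and adjusted over the list alone. Without shr replicate 3 the mean in shr was 0.25 (adjusted p = 0.0267; adjusted p = 0.335 with an estimated correlation).

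Nitrate response genes had means of -0.07 in scr (camera adjusted p = 0.967) and 0.02 in shr (camera adjusted p = 0.677), with medians of the opposite sign at 0.03 and -0.12. In shr NIR1, the nitrite reductase gene, fell by 0.41 and RFNR2 rose by 0.83 over all genes, and 3 rose and 3 fell adjusted over the list alone. RFNR2 lost its call without WT replicate 2 or 3 (up to 0.0624). The senescence list had means of -0.25 in scr (camera adjusted p = 0.425) and -0.31 in shr (camera adjusted p = 0.506). ORE1, a NAC transcription factor gene, fell by 1.80 in shr as 1 of 7 over all genes and adjusted over the list alone. The lists of photosynthesis (-0.02 in scr and -0.05 in shr, camera adjusted p = 0.676 and 0.401), gibberellin (-0.05 and 0.06, 0.539 and 0.791), iron deficiency (-0.27 and -0.35, 0.791 and 0.925) and circadian clock (-0.06 and 0.03, 0.990 and 0.794) held no member past the threshold over all genes in either mutant. Adjusted over the list alone, 1 gibberellin gene rose in shr and none of the other 3 lists had a call. Clock genes differed in opposite directions between repeats, CCA1 by 0.64 and GI by -0.70 for WT replicate 1 minus 2. A shift in harvest time can thus cancel in the mean of that list. On the shr arrays LHY lay at 9.43, 7.55 and 6.87, against 9.51, 8.58 and 8.95 in WT. GI lay at 7.47, 8.59 and 8.75 in shr, against 7.27, 7.97 and 7.61 in WT. The iron deficiency median was 0.18 in shr, opposite in sign to its mean, where BHLH39 had a value of -1.95 and NAS4 of 0.59. Of the other lists that did not pass in scr, none had a member past the threshold over all genes there except LOX2 in the jasmonate list. Adjusted over the list alone, 2 cell wall expansion genes and 1 gene each of the G1/S, leaf growth, nitrate and flowering lists fell in scr, 1 gene each of the root and xylem lists rose, and the sugar starvation, water deficit, salicylic acid, senescence and meristem lists had none.

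The direct comparison of shr with scr asked whether the mutants differ from each other. HSP17.6A was 2.46 higher in shr (SE 0.15, limma adjusted p = 3.74e-04), PR4, a defence gene, 1.71 higher (SE 0.15) and FLC 1.63 higher (SE 0.14). LTP4 (1.98) and the cell wall invertase gene ATBFRUCT1 (1.55) were also higher. HSP17.6A lay at 3.89 to 3.96 on the scr arrays, which was not tested against background, so the size of its difference is uncertain. THA2 was lower in shr than in scr by 2.87 (log2 difference -2.87, SE 0.08), AT1G06080 was at -2.57, PGL5 at -1.93, PGL2, another 6-phosphogluconolactonase gene, at -1.73 and ORE1 at -1.73. In all, 279 loci differed (limma, adjusted p under 0.05), 159 higher and 120 lower in shr, and 58 of these at least 2-fold. With each array shifted to a common median 368 loci differed, and the share of higher calls was 37.2% in place of 57.0%. The count was 177 without WT replicate 1, 154 without WT replicate 3, and 39, 33 or 56 without scr replicate 1, 2 or 3. It was 421, 124 or 610 without shr replicate 1, 2 or 3, and 24 with scr and shr arrays alone. THA2, HSP17.6A, PR4, FLC and PGL2 kept their calls in all 9 fits that left out 1 array. AT1G06080 and ATBFRUCT1 lost theirs without scr replicate 1, 2 or 3 (adjusted p up to 0.0672 and 0.0853), and LTP4 without WT replicate 1, any scr array or shr replicate 2 (up to 0.1001). ORE1 lost its call without any 1 WT or scr array (up to 0.133), and PGL5 without any 1 WT or scr array or shr replicate 2 (up to 0.0968).

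Of the 28 lists, 7 differed between the mutants at camera's preset correlation. The salicylic acid and jasmonate lists, at 0.12 and 0.14, did not pass with all arrays but did so without shr replicate 3. There both had a mean of 0.25 (adjusted p = 0.00275 and 0.0140; adjusted p = 0.239 and 0.186 with an estimated correlation). Heat shock genes were higher in shr than in scr by a mean of 0.66 (SE 0.21, camera adjusted p = 1.32e-07; adjusted p = 0.0982 with an estimated correlation). Over all genes 4 of 12 members were higher, HSP17.6A, HSP17.6II (0.93), HSP90.1 (0.89) and HSP17.6C, and 7 were so adjusted over the list alone. Cytokinin response genes were lower, with a mean of -0.43 (SE 0.13, camera adjusted p = 1.30e-04; adjusted p = 0.363 with an estimated correlation). Over all genes 2 of 10 members were lower, ARR16 (-1.38) and ARR6 (-0.67), and 4 were so adjusted over the list alone. These lists kept their calls in all 9 fits that left out 1 array. The phosphate starvation list was higher by 0.42 (SE 0.12, camera adjusted p = 0.00103; adjusted p = 0.643 with an estimated correlation). Its call was lost without shr replicate 1 (mean 0.24, adjusted p = 0.0684) or shr replicate 2 (mean 0.27, adjusted p = 0.0524). Its mean was 0.76 without shr replicate 3 (adjusted p = 2.06e-13; adjusted p = 0.110 with an estimated correlation). The SHR-SCR network list was at -0.35 (camera adjusted p = 0.0197; adjusted p = 0.388 with an estimated correlation). SHR and SCL23 were lower over all genes, and 4 were lower and 1 higher adjusted over the list alone. Its call was lost without scr replicate 1 (0.0744) or shr replicate 1 (0.0752).

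Some cell cycle lists differed between the mutants by small amounts, while those of histones (camera adjusted p = 0.228), G1/S regulators (0.429) and CDK inhibitors (0.294) did not pass. The DNA replication list was lower in shr by a mean of -0.13 (camera adjusted p = 0.0193; adjusted p = 0.724 with an estimated correlation), and the mitosis list by -0.11 (camera adjusted p = 0.0253; adjusted p = 0.569 with an estimated correlation). The DNA damage response list was lower by a mean of -0.16 (camera adjusted p = 0.0477; adjusted p = 0.504 with an estimated correlation). In these 3 lists and in the phosphate starvation list no member passed over all genes or adjusted over the list alone. The DNA replication call was lost without scr replicate 3 (adjusted p = 0.0966), shr replicate 1 (0.168) or shr replicate 3 (0.152), and the mitosis call without scr replicate 2 (0.108) or shr replicate 3 (0.195). The DNA damage call was lost without WT replicate 2 (0.0611), scr replicate 2 (0.0962), scr replicate 3 (0.0584) or shr replicate 3 (0.207).

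The changes of both mutants against WT were related across genes, which are not independent replicates. Pearson's r of the log2 changes was 0.632 and Spearman's rho 0.536. Because both comparisons use the same 3 WT arrays, unchanged groups simulated against shared WT arrays gave a mean r of 0.501 (highest 0.537 of 100 simulations) with a pooled spread and of 0.309 (highest 0.353) with the spread of each group. The covariance was 0.0460, against simulated values of 0.0116 and 0.00727, which leaves 0.0344 or 0.0387 as the estimate of the shared effect. The simulations drew the arrays independently. A condition shared by scr and shr arrays of equal number, whose deviations correlated at up to 0.444, is therefore not taken off. Of the 76 loci called in scr, 70 were also called in shr. Of these, 45 rose in both, where independent lists would share 2.13, and 23 fell in both, where independent lists would share 1.02. In 20 simulations of unchanged groups with shared WT arrays, no locus was called in both, but unchanged groups give almost no calls at all, so this sets no level for lists of this size. The 68 loci called in the same direction became 31, 21 or 19 without WT replicate 1, 2 or 3, and 32, 30 or 17 without scr replicate 1, 2 or 3. They became 464 without shr replicate 3, 213 with only the 2 groups compared, 366 with array weights and 46 with the replicate number as a block. THA2 (0.64 in scr and -2.23 in shr) and AT5G25770 (0.53 in scr and -0.87 in shr) had opposite signs. In scr THA2 lost its call without WT replicate 2 or 3 or any scr array (adjusted p up to 0.104). AT5G25770 lost it in 7 of 9 fits, all but those without scr replicate 2 or shr replicate 3 (up to 0.197), and with the replicate number as a block (adjusted p = 0.0957). AT5G25770 falls outside the rule for named genes and was chosen after its values were seen. Of the 76 loci, 53 had a larger change in shr. With 3 WT arrays the controls cannot be split with at least 2 arrays on each side, so part of the excess may come from the shared controls.

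**Figure D4:**
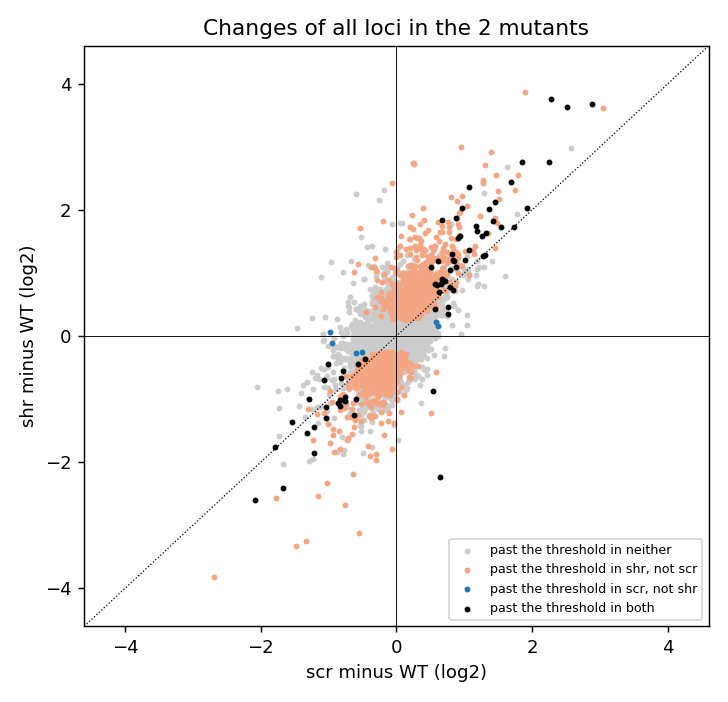
Change in scr (x axis, log2) against change in shr (y axis, log2), both relative to WT, for all 20777 loci, coloured by the comparison in which a locus passed the threshold; the dotted line marks equal change. Of the 70 loci called in both mutants, 45 lie in the upper right and 23 in the lower left.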

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

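The tests of noise, of a wrong label and of young leaf genes, and the comparison of the clock genes on other array pairs, were chosen only after the result was seen. The direct comparison of shr with scr showed 279 loci (limma, adjusted p under 0.05) whose values differ between the mutants, and 7 gene lists did so by camera's test with a preset correlation, none of them with an estimated correlation. The mean differences (shr minus scr, log2) were 0.66 for the heat shock list, 0.42 for phosphate starvation, -0.43 for cytokinin response, -0.35 for the SHR-SCR network, -0.16 for DNA damage response, -0.13 for DNA replication and -0.11 for mitosis. Among named genes, those higher in shr than in scr were HSP17.6A (2.46), LTP4 (1.98), PR4 (1.71), FLC (1.63), ATBFRUCT1 (1.55), BGLU28 (1.12), HSP17.6II (0.93), HSP90.1 (0.89), DR4 (0.75) and PYK10 (0.54). Those lower were THA2 (-2.87), AT1G06080 (-2.57), PGL5 (-1.93), PGL2 (-1.73), ORE1 (-1.73), SHR itself (-1.51), ARR16 (-1.38), PRE1 (-0.92), SOC1 (-0.88), ARR6 (-0.67) and NIR1 (-0.56). In this comparison BGLU28, HSP17.6II, HSP90.1, DR4, PYK10, ARR16, PRE1, SOC1, ARR6 and NIR1 were not followed through the alternative fits. How far their calls hold there was not tested.

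Regrouping the 6 arrays of a comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split of scr and shr gave 279 loci and the highest of the others 0. For scr against WT these were 76 and 0, where 4 of the 10 splits part all 3 pairs of equal number and 6 part 1 pair, with 0 the highest of either kind apart from the real one, and for shr against WT 1691 and 1, so that in each comparison 1 of the 10 splits, the real one, gave as many.

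The array shr replicate 3 stood apart from the other 8. On it, 981 loci lay over 1 log2 from the mean of shr replicates 1 and 2, against 121 loci between those arrays, with DIN10 at 5.61, EXLA1 at 5.04 and XTH22 at 4.48 above it and PAP1, the anthocyanin regulator, at -4.87. Noise spread over all genes is argued against by the 5 sugar starvation genes seen neither among its most deviating genes nor among the top rises in shr, whose mean absolute deviation of 1.27 lay at percentile 99.8 of 10000 random lists matched on mean expression. A WT or scr plant under a wrong label is argued against by SHR, which lay 1.31 below the lowest WT or scr value. Harvest at another time of day and low sugar in these plants stay open. The clock list's deviation reached percentile 100, but so did that of shr replicate 1 from 2 and of scr replicate 3 from 1 and 2 (1.25, 1.25 and 1.06), which leaves that test undecided. The 6 sugar starvation genes not seen among the most deviating genes, of which ASN1 was known as a top rise in shr, were higher on that array by 1.47 on average, at percentile 100, so that low sugar is a candidate explanation. No biological explanation from the design separates arrays of 1 genotype.

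By camera's preset correlation the mitosis and histone lists were lower in both mutants, and the mitosis list lower in shr than in scr (-0.11). With an estimated correlation none of these calls holds (adjusted p = 0.110 and 0.0982 in scr, 0.117 for both in shr, 0.569 between the mutants). With fry, which does not compare a list with other genes, both lists passed in each mutant. The fry adjusted p was 0.00523 and 0.00334 in scr and 0.00196 for both in shr. Between the mutants the mitosis list had a fry adjusted p of 0.180 and did not pass. In scr 0 of 22 and 0 of 16 members passed over all genes, with a spread estimated from all arrays, shr replicate 3 included. The difference between the mutants was also lost without scr replicate 2 (adjusted p = 0.108) or shr replicate 3 (adjusted p = 0.195). That shr replicate 3 alone made the pattern in shr is argued against by a mean of -0.39 without it (camera adjusted p = 1.79e-09; adjusted p = 0.110 with an estimated correlation), and a trend with signal level by matched random lists, among which the mitosis median lay at percentile 0 in both mutants and the histone median at 0.01 or below. A smaller share of young dividing leaf tissue cannot be told apart from a change within cells. The 12 genes of young leaf tissue had means of -0.12 (SE 0.07) in scr and -0.083 (SE 0.13) in shr, against -0.32 and -0.43 for mitosis, an error too wide to decide. An effect of the mutations on the cell cycle, the question of the series, therefore remains a hypothesis beside it.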

How the results depend on the processing

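The fits of 2 groups without shr replicate 3, the list tests with an estimated correlation in added fits, and the look at clock genes between repeats were chosen only after the data were seen. No locus called in the fit of all 9 arrays changed sign under any alternative. The counts for scr against WT, shr against WT and shr against scr (76, 1691 and 279) stayed within 1.5 times under a second quantile normalisation (91, 1697 and 314), a common median (88, 1966 and 368), without the lower 40% of loci by signal (55, 1616 and 245), and with eBayes trend and robust options (81, 1673 and 291). They were 577, 807 and 24 with only the 2 groups compared, and 491, 2657 and 594 with array weights, where shr replicate 3 had a weight of 0.245. Leaving out 1 array gave 17 to 595, 654 to 2643 and 33 to 610, the highest each time without shr replicate 3, whose removal kept 76 of 76, 1514 of 1691 and 268 of 279 calls. With 2 groups and without shr replicate 3 the counts were 2265 for shr against WT and 353 for shr against scr. By construction, stricter thresholds gave fewer: 23, 485 and 28 at an adjusted p under 0.01, 33, 276 and 58 with at least a 2-fold change, and 22, 315 and 24 with treat. In scr against WT the log2 changes are the same with and without the shr arrays. The rise from 76 to 595 or 577 loci there therefore came from the estimate of the spread, which the groups share. Apart from this and the thresholds, the causes were not tested.

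The correlation of the mutants' changes, 0.632, was 0.705 with array weights and 0.512 to 0.728 when 1 array was left out. The DNA replication list (-0.14 in scr, -0.27 in shr) kept its calls except with an estimated correlation (adjusted p = 0.562 and 0.451) and, in scr, with fry (adjusted p = 0.231). Of the 84 list tests 26 passed, 0 with camera's estimated correlation (13 at an unadjusted p under 0.05), 19 with fry and 23 to 33 when 1 array was left out. With camera's estimated correlation 0 passed without shr replicate 3 (18 at an unadjusted p under 0.05) and 0 with array weights (15 at an unadjusted p under 0.05). The anthocyanin list in shr against scr (-0.09, not past the threshold) turned to 0.61 with array weights (adjusted p = 0.0143; adjusted p = 0.704 with an estimated correlation) and to 0.85 without shr replicate 3 (adjusted p = 9.84e-06; adjusted p = 0.446 with an estimated correlation). It ranged from -0.75 to 0.85 when 1 array was left out, and shr replicate 3 held that list far below the other shr arrays. Over all alternatives, the 289 results of named genes had 4542 values, of which 4115 kept their side of the threshold, 284 lost the call, 143 gained one and 0 reversed. Among the 4115, 40 had the opposite sign with no call in either fit. The 84 list tests had 1512 values: 1396 kept their side, 48 of them with the opposite sign and no call in either fit, 73 lost the call, 41 gained one and 2 reversed.

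Over all groups, 6 of 9 pairs of equal number had deviations correlated over 0.1 (range -0.106 to 0.444). The main fit holds no term for the numbers, which were on this basis taken as pairs for scr against WT only. Yet 8 of 9 arrays correlated best with their own number, and all 10 measured clock genes differed between replicates 1 and 2 with the same sign in every group, LHY by 0.93 in WT, 1.15 in scr and 1.88 in shr. This is a hint of a shared condition from the data and not from the design. Replicate 3 did not move the same way in every group. LHY lay there at 8.95 in WT, 7.72 in scr and 6.87 in shr, against 8.58, 8.48 and 7.55 on replicate 2. Whether WT and mutant arrays of that number were harvested at the same time was not tested. With the replicate number as a block the counts were 52, 1720 and 236, with 46 of 76, 1418 of 1691 and 187 of 279 calls kept. In scr against WT the block ended the calls of LSU1, SULTR4;2, WRKY17, NET3A, HSP17.6B, APR3 and AT5G25770. It changed no other call there of a gene named by the rule, of a list fixed beforehand, or of GGCT2;1, SHM7, NF-YA6 or NF-YA8. For NF-YA5 and the lists of sulfate starvation, glucosinolate and NF-Y genes the block was not tested. In shr against WT the block ended the calls of the xylem list (adjusted p = 0.0549), SNE (0.0563), COR15A (0.0638), OPR3 (0.0654), CESA7 (0.0730) and WRKY17 (0.0640), and in shr against scr those of the DNA damage list (0.0526) and ORE1 (0.0566). The anthocyanin list in shr gained a call (adjusted p = 0.0104; adjusted p = 0.762 with an estimated correlation and no block), as did PCNA1 (0.0274), GAPB (0.0451), CHS (0.0363) and HAI1 (0.0438). Both alternatives on probe sets per gene were not run, because the table holds 1 row per locus. Signal over background was not tested, since no detection values were used here, so changes of dim loci are the least certain, and where 1 group lies near the lowest values, as for HSP17.6A and EARLI1, so is the size of a large change.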

Other observations

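The tests near the mutated loci, and the choice of the sulfate starvation, glucosinolate and NF-Y lists from the genes with the largest changes, were made only after those results were seen. Of 16 genes known to respond to low sulfate 7 rose in scr and 11 in shr (limma, adjusted p under 0.05 over all genes), with means of 1.16 (SE 0.25) and 1.55 (SE 0.32). GGCT2;1, a gene of glutathione breakdown, rose by 2.25 in scr and 2.76 in shr, SHM7 by 1.07 and 1.36, APR3, an enzyme of sulfate reduction, by 0.87 and 1.09, and the vacuolar sulfate transporter gene SULTR4;2 by 1.30 and 1.28. The transporter gene SULTR1;2 rose by 2.43 in shr and had a value of 1.27 in scr, while SULTR1;1 had values of 0.05 and -0.09. In the NF-YA family 5 of 10 genes rose in scr and 7 in shr, with means of 0.88 (SE 0.19) and 1.12 (SE 0.24). NF-YA6 rose by 1.19 and 1.66 and NF-YA8 by 0.85 and 1.18. The 5 called in scr, NF-YA2, NF-YA3, NF-YA5, NF-YA6 and NF-YA8, are the genes that prompted this list. Its other members did not pass in scr (limma adjusted p from 0.199 to 0.887), and of them NF-YA9 (0.42) and NF-YA10 (1.90) rose in shr. They were not tested as a set, so the counts and means of the family carry that choice. In scr GGCT2;1 lost its call without any WT array or scr replicate 2 or 3 (adjusted p up to 0.0742), and APR3 without WT replicate 2 or 3 or any scr array (up to 0.0989) and with the replicate number as a block (adjusted p = 0.0528).

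The sulfate starvation list was chosen from the top genes, so its test rests on the 8 members not seen there. Their mean was 0.42 in scr and 0.61 in shr (camera adjusted p = 6.61e-06 and 1.30e-05 over the 10 tests of added lists; adjusted p = 0.0175 in both with an estimated correlation), as a response of these genes as a set would give. Adjusted over all 94 list tests, the estimated correlation gave an adjusted p of 0.0705 in both, past the threshold no longer. Taken singly, 1 of these 8 members rose in scr and 3 rose in shr over all genes. That shr replicate 3 alone made the pattern in shr is argued against by a mean of 0.70 for these 8 members without it. For all 16 genes, those that prompted the list included, the mean in shr was 1.71 without that array and 1.55 with it. A fall of aliphatic glucosinolate genes, which would be consistent with sulfate shortage, stays open: their mean was -0.27 in scr (camera adjusted p = 0.121) and -0.86 in shr (camera adjusted p = 0.00166; adjusted p = 0.360 with an estimated correlation), but -0.35 in shr without shr replicate 3. Whether the medium, uptake by the altered root or another step lies behind this was not tested, and a response to sulfate supply in both mutants is a hypothesis from these data.

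A rise of all NF-Y subunit genes is argued against by the 7 NF-YB and NF-YC genes of the added list, whose mean was -0.14 in scr and -0.066 in shr (SE 0.07). Members of these families outside that list were not tested as a set.

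Sequence of another accession linked to a mutated locus could change genes near it. Among the 100 measured loci on each side of SHR, 21 of 200 changed in shr (10.5%, against 8.11% elsewhere, one-sided Fisher's exact p = 0.137), among them AT4G36700 at -3.83, which prompted the test and lost its call without WT replicate 1 or 3 (adjusted p up to 0.0609). Near SCR, 1 of 200 changed in scr, HTA11 (0.5% against 0.365%, one-sided Fisher's exact p = 0.521). HTA11 was also called lower in shr (-0.67), so its change is not particular to scr. AT4G36700 had a value of -2.68 in scr, not past the threshold (limma adjusted p = 0.190). Both shares lie above the rest of the table by less than these tests can tell from chance, and the explanation stays open. The 21 loci near SHR also hold CYCB1;1 (-0.72) and SAUR-AC1 (-1.08), for whose falls in shr it stays open as well.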
